A study of Mus musculus with 8 samples.

How the data were processed

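RNA was measured by sequencing in livers of mice on the C57BL/6 strain, per the labels. The mice lacked Xbp1 in the liver (knockout) or were flox controls, and were fed regular chow or a high-fat diet combined with an equivalent of high-fructose corn syrup for 4 weeks. Each cohort held 4 mice, whose samples were pooled into 2 replicate libraries, which makes 8 libraries in 4 groups. The analysis used 4 deposited files with 1 value per gene and group, so the values per library were not analysed here. Each file was assigned to its group by its name, which carries the group's part of the sample titles.

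The deposited values are RPKM (mapped reads scaled by transcript length and library size), per the file headers. TopHat2 2.0.7, Cuffdiff 2.1.1 and the mouse genome build mm10 are named in the submitters' processing notes, with no role or order. The gene annotation, the scaling between libraries and the way the 2 libraries of a group were combined are not given in the sources used here. Each file listed the same 23179 rows and 22923 symbols, and rows with a repeated symbol (158 symbols) were summed. Symbols joined by commas in the files cover overlapping or identical genes and were kept as 1 entry.

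Depth per library is unknown. Low values multiplied by transcript length were searched for steps of whole reads, up to 5 steps, with a tolerance of 0.05 of a step. The share of values within that tolerance was 22.0% in flox chow, 13.8% in flox high fat, 21.7% in knockout chow and 17.7% in knockout high fat, too few for recovery of read numbers. No interval or floor that needs a read number is given. An exact 0 was treated as a possible failed estimate, because Alb, the gene of serum albumin, was listed at 0 in all 4 groups. Genes listed at 0 in a group were left out of every comparison with that group.

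Genes with at least 1 RPKM in at least 1 of the 4 groups were kept (10351 genes). The log2 change of a gene was log2((a + 1)/(b + 1)) with a pseudocount of 1 RPKM, which understates the change of low genes. The comparisons were knockout against flox on each diet, the high-fat diet against chow in each genotype, and the difference of the 2 knockout changes (high fat minus chow), called the interaction. Without values per library there was no test, so no p-value, standard deviation or standard error is given. A gene was called past the threshold when its absolute log2 change was at least 1. The words rose and fell are used for such genes.

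The text names genes by a rule. In each comparison, among genes past the threshold with at least 5 RPKM in at least 1 of the groups compared and leaving out small RNA genes, it takes the 10 with the largest rise and the 10 with the largest fall (5 and 5 for the interaction). Small RNA genes were recognised by the start of their symbol. From each gene list it takes up to 4 members with the largest absolute change. Xbp1, Ern1, Ddit3, Hspa5, Atf4 and Alb are always included. The 39 gene lists cover pathways, liver zones, other cell types of liver and neighbouring tissue, sex and RNA quality. The gene lists, the naming rule, the threshold, 8 alternatives for the gene counts and 1 for the random lists were fixed before the data were examined. The members of the list of IRE1 decay substrates came partly from work on Xbp1-deficient liver, so its direction is not independent of that model.

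For a list with at least 5 measured members, the median log2 change was set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The text gives the range between the 2.5 and 97.5 percentiles of the random lists, and a list outside it is said to stand apart. This describes these libraries and is not a test between conditions. Where 34 lists were compared, 1.7 would lie outside by chance if genes moved independently, which genes of 1 pathway do not.

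Transcript length, GC content and coordinates came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes, matched on gene symbol or its synonyms. The length and GC check covered 99.1% of the genes in each comparison it was run on. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. The steps were tested on simulated data for knockout against flox on chow (9778 genes, counting noise only, at an assumed depth). In it, 88.1% of 67 genes changed 3-fold and 95.5% of 66 genes changed 6-fold passed the threshold, 0 of 66 genes changed 1.5-fold did, and 0 of 9579 unchanged genes did. With no change simulated, 2 of 34 lists lay outside the range.

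The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 RPKM, a threshold of 1.5-fold, the highest of repeated rows in place of their sum, rescaling each group to a median log2 ratio of 0, rescaling each group to the same sum without the 50 most abundant genes, and, for the lists, matching in 10 bins. Zeros kept at 0 and small RNA genes left out were added after the data were seen. The closing section gives their effect.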

Results

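Liver RNA was profiled in a design of 2 genotypes by 2 diets. Xbp1 encodes a transcription factor of the unfolded protein response, whose messenger RNA is spliced by the endoplasmic reticulum (ER) stress sensor IRE1. Flox controls and mice lacking Xbp1 in the liver received chow or a high-fat diet with a high-fructose corn syrup equivalent for 4 weeks. Each group of 4 mice was sequenced as 2 pooled libraries and is represented by 1 deposited RPKM value per gene. No difference below has a replicate check, and the spread between libraries is unknown. The deposited values summed to 513694 RPKM in flox chow, 461725 in flox high fat, 461392 in knockout chow and 367414 in knockout high fat, and 9713, 9829, 9784 and 10055 genes reached 1 RPKM. The 50 most abundant genes held between 37.3% and 39.1% of each sum.

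The targeted gene was lower in both knockout groups. Xbp1 (mm10 chromosome 11, 5520659 to 5525893) stood at 112 RPKM in flox chow and 44.2 RPKM in knockout chow, 39.6% of the flox level. On the high-fat diet it stood at 90.7 RPKM in flox and 34.1 RPKM in knockout livers, 37.6% of the flox level. A value for the whole gene includes reads from any exon that remains after deletion and from liver cells that are not hepatocytes. Ern1, which encodes IRE1, was listed at 3.86, 5.39, 4.69 and 6.10 RPKM in flox chow, flox high fat, knockout chow and knockout high fat.

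**Figure D1:**
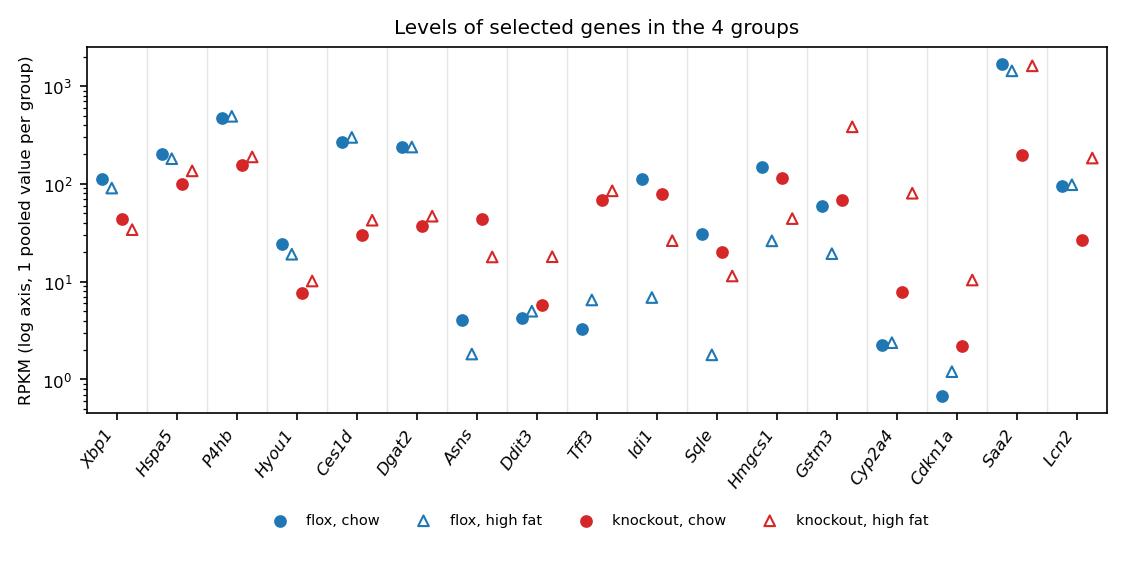
RPKM on a log axis of 17 genes, in flox (blue) and knockout (red) livers on chow (filled circles) or the high-fat diet (open triangles), with 1 pooled value per group and no error bars because values per library were not analysed here. Xbp1 lies between 34.1 and 112 RPKM and Sqle between 1.79 and 30.7 RPKM.

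On chow, the loss of Xbp1 went with lower RNA levels of genes for the protein-folding and secretory machinery of the ER. Of 29 ER chaperones and foldases, 13 fell and 0 rose (median -0.91, random lists -0.15 to 0.02). Erp44 (38.6 to 11.3 RPKM, log2 change -1.69), P4hb (476 to 157 RPKM, log2 change -1.60) and Hyou1 (24.2 to 7.72 RPKM, log2 change -1.53) fell the furthest, and Hspa5, the chaperone BiP, went from 204 to 99.8 RPKM (log2 change -1.02). In the list of ER translocation and N-glycosylation genes, 8 of 35 fell (median -0.58, random lists -0.14 to 0.01), among them Rpn1 (30.5 to 10.4 RPKM, log2 change -1.47) of the oligosaccharyltransferase and the translocon subunits Sec61b (-1.37) and Sec61g (-1.36). Genes of ER-associated degradation (median -0.31, random lists -0.15 to 0.03) and of ER to Golgi transport (median -0.35, random lists -0.15 to 0.01) stood apart on the low side, with 1 gene, Derl3 (-1.10), and 0 genes past the threshold.

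The largest fall on chow was that of a carboxylesterase gene. Ces1g on mm10 chromosome 8, 93302369 to 93337308 fell from 84.1 to 7.56 RPKM (log2 change -3.31), and Ces1e (-3.29), Ces1c (-3.28) and Ces1d (-3.12) of the same cluster of ester-hydrolysing enzymes fell alongside, although reads of these near-identical genes may have been split between copies. Ces1 genes led the list of IRE1 decay substrates, in which 9 of 17 fell (median -1.20, random lists -0.15 to 0.07). Members of that list came partly from work on Xbp1-deficient liver, so its direction is not independent evidence. Retinol saturase, Retsat (129 to 15.6 RPKM, log2 change -2.97), the uncharacterised 2210411K11Rik (-2.82) and Cyp2c67 (-2.52) were among the 10 largest falls as well. In fatty acid and triglyceride synthesis, 8 of 30 genes fell and 1 rose (median -0.45, random lists -0.16 to 0.02), including Dgat2 (239 to 37.3 RPKM, log2 change -2.65), which encodes an enzyme of the last step of triglyceride synthesis, Scd1 (-1.81), Acacb (-1.49) and Fasn (-1.35). Of 25 genes of cholesterol synthesis and uptake, 2 fell (median -0.63, random lists -0.15 to 0.03), among them Insig1 (-1.16). The lipoprotein list stood apart on the low side (median -0.26, random lists -0.17 to 0.03), with 2 falls, among them Lrp1 (-1.44).

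RNA levels of genes for secreted acute phase proteins were lower as well. 9 of 28 fell and 1 rose (median -0.59, random lists -0.19 to 0.02), with Saa2 (1699 to 197 RPKM, log2 change -3.10), Saa1 (-2.37), Itih4 (-2.23) and Lcn2 (94.2 to 26.6 RPKM, log2 change -1.79). Hepatocyte plasma protein genes stood apart on the low side (median -0.26, random lists -0.20 to 0.02), with 1 fall, in the prothrombin gene F2 (-1.21). Cyp4a10, a fatty acid hydroxylase and target of the receptor PPARA, fell from 145 to 30.2 RPKM (log2 change -2.23), while the list of fatty acid oxidation and PPARA targets stood apart on the high side by a small margin (median 0.03, random lists -0.15 to 0.01).

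The risers on chow were fewer. The trefoil peptide gene Tff3 (mm10 chromosome 17, 31125306 to 31129646) rose from 3.27 to 68.9 RPKM (log2 change 4.03), asparagine synthetase, Asns (4.02 to 44.0 RPKM, log2 change 3.17), by less, and then Serpina7 (10.2 to 91.2 RPKM, log2 change 3.04), the gene of thyroxine-binding globulin. Caveolin, Cav1 (2.47), the chemokine Cxcl14 (1.96), Socs2 (1.64), metallothionein Mt2 (1.52), Cyp2a4 (1.45), Csad (1.39) of taurine synthesis and Rgs16 (1.36) completed the 10 largest rises. In the list of ATF4 and CHOP targets, 2 of 28 rose, Asns and the hormone gene Fgf21 (1.39) (median 0.22, random lists -0.09 to 0.05), while Ddit3, which encodes CHOP, was listed at 4.23 and 5.78 RPKM and Atf4 at 41.5 and 38.3 RPKM. Matrix genes (median 0.28, random lists -0.09 to 0.07), cholangiocyte and progenitor markers (median 0.25, random lists -0.08 to 0.12) and stellate cell markers (median 0.15, random lists -0.10 to 0.08) stood apart on the high side with 0 rises past the threshold, and the fibronectin gene Fn1 (-1.68) fell. On the high side, too, stood the lists of NRF2 and oxidative stress (median 0.08, random lists -0.15 to 0.03) and of apoptosis and p53 targets (median 0.10, random lists -0.08 to 0.06), with 0 genes past the threshold. Inflammation and chemokine genes stood there as well (median 0.12, random lists -0.08 to 0.07), of which 1 rose and 1 fell. Macrophage markers (median 0.01, random lists -0.11 to 0.05) and endothelial markers (median -0.04, random lists -0.09 to 0.06) lay inside the range.

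In all, 26 genes rose and 141 fell among 10322 on chow. Rescaling without the 50 most abundant genes moved the split to 86 and 129, and 23 of 34 lists stood apart from random lists.

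On the high-fat diet the ER lists were again lower in knockout than in flox livers. 3 of 29 ER chaperones and foldases fell (median -0.62, random lists -0.38 to -0.12), P4hb (491 to 189 RPKM, log2 change -1.37), Dnajb9 (-1.29) and Erp44 (-1.24), while Hspa5, BiP, stood at 181 and 136 RPKM in flox and knockout livers. The median of all genes in this comparison was -0.13, and rescaling to a median log2 ratio of 0 moved it by 0.15. Among the 3252 genes with at least 10 RPKM in all 4 groups the median was -0.27. List medians are read against the random lists, which carry the same shift. Falls of single genes have no such reference, and 116 genes in place of 192 fell after that rescaling. In ER translocation and N-glycosylation 2 of 35 genes fell (median -0.64, random lists -0.35 to -0.13), Sec61g (-1.13) and Rpn1 (-1.10). ER-associated degradation (median -0.44, random lists -0.37 to -0.11) and ER to Golgi transport (median -0.48, random lists -0.36 to -0.14) also stood apart on the low side. Among the IRE1 decay substrates 9 of 17 fell and 1 rose (median -1.05, random lists -0.37 to -0.03), in a list that is not independent of this model, with Ces1e (-2.82), Ces1d (299 to 42.6 RPKM, log2 change -2.78) and Ces1f (-2.29) falling the furthest.

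The lists of NRF2, of ATF4 and CHOP and of p53 targets stood apart on both diets. They had more rises in knockout livers on this diet than on chow. 8 of 27 genes of the NRF2 and oxidative stress list rose and 0 fell (median 0.76, random lists -0.39 to -0.11). Gstm3, a glutathione S-transferase gene on mm10 chromosome 3, 107963696 to 107969283, rose from 19.4 to 384 RPKM (log2 change 4.24), with Gsta1 (3.97), the carbonyl reductase Cbr3 (0.299 to 10.9 RPKM, log2 change 3.20) and the glutathione peroxidase Gpx2 (2.24), although glutathione transferase genes share reads between copies. Of the ATF4 and CHOP targets, 8 of 28 rose and 1 fell (median 0.21, random lists -0.24 to -0.02), among them Asns (1.82 to 17.9 RPKM, log2 change 2.74), Nupr1 (1.16 to 7.34 RPKM, log2 change 1.95) and Ddit3 (4.99 to 18.0 RPKM, log2 change 1.67). The list of apoptosis and p53 targets stood apart on the high side (median 0.15, random lists -0.22 to -0.01), with rises in Cdkn1a (1.20 to 10.4 RPKM, log2 change 2.37), a cell cycle inhibitor, Phlda3 (1.54) and Tnfrsf12a (1.20) and a fall in Bik (-1.06). Cell cycle genes had 4 rises among 18 (median 0.58, random lists -0.15 to 0.14), led by Ccnd1 (4.67 to 19.7 RPKM, log2 change 1.87), cyclin D1. The other large rises were Cyp2a4 (2.38 to 80.3 RPKM, log2 change 4.59), S100g (0.263 to 20.2 RPKM, log2 change 4.07), which encodes a calcium-binding protein, Gm3776 (3.85), Ly6d (3.69), Tff3 (3.52) and Serpina7 (3.06). Gm3776 lies between Gsta1 and Gsta2 on mm10 chromosome 9, so its rise may not be separate from that of Gsta1.

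Markers of other cell types moved with these groups. Cholangiocyte and progenitor markers had 5 rises among 15 (median 0.87, random lists -0.16 to 0.22), with osteopontin, Spp1 (20.6 to 103 RPKM, log2 change 2.27), Tspan8 (1.53), Cd24a (1.44) and Epcam (1.21). Macrophage markers (median 0.36, random lists -0.29 to -0.04), with rises in Cd9 (1.36) and Trem2 (1.29), and stellate cell markers (median 0.36, random lists -0.22 to 0.05) stood apart on the high side. So did matrix genes (median 0.54, random lists -0.20 to 0.04), with rises in Mmp12 (1.77), Col3a1 (1.23) and Col1a1 (1.21) and a fall in Fn1 (-1.41), and chemokine genes (median 0.46, random lists -0.19 to 0.02), with rises in Cxcl14 (2.09) and Ccl2 (1.19). Endothelial markers lay inside the range (median -0.05, random lists -0.23 to -0.01), with a median that turned positive under both rescalings. Blood genes (median -0.79, random lists -0.58 to 0.04) stood apart on the low side.

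Some lists of hepatocyte functions stood apart on the low side in knockout livers on this diet, and others lay inside the range of random lists. 5 of 19 periportal genes fell (median -0.74, random lists -0.49 to -0.13), among them Hal (90.4 to 29.3 RPKM, log2 change -1.59), Sds (-1.16), Cps1 (-1.04) and Asl (-1.04), which act in amino acid breakdown and the urea cycle. Falls close to the threshold, such as those of Cps1 and Asl, depend on the scaling described above. In the list of male-biased liver genes 6 of 18 fell (median -0.72, random lists -0.54 to -0.15), with Mup21 (-1.75) and Mup3 (-1.74) of a family of near-identical major urinary protein genes. Bile acid genes (median -0.47, random lists -0.41 to -0.12) stood apart on the low side, with falls in the sterol transporter genes Abcg8 (61.6 to 13.0 RPKM, log2 change -2.16) and Abcg5 (96.7 to 33.0 RPKM, log2 change -1.52). Lipoprotein genes (median -0.47, random lists -0.45 to -0.13), with Apoa1 (-1.23) and Lipc (-1.23), and lipid droplet genes (median -0.40, random lists -0.37 to -0.08), with G0s2 (-1.09), did as well. In fatty acid and triglyceride synthesis 4 of 29 genes fell, Dgat2 (238 to 46.8 RPKM, log2 change -2.32), Srebf1 (-2.11), Agpat2 (-1.50) and Thrsp (-1.18), and the list lay inside the range (median -0.30, random lists -0.40 to -0.13). Cholesterol synthesis stood apart on the high side, with 4 of 25 genes rising (median 0.30, random lists -0.39 to -0.12), Sqle (1.79 to 11.4 RPKM, log2 change 2.16), Idi1 (6.89 to 26.3 RPKM, log2 change 1.79), Nsdhl (1.22) and Cyp51 (1.18). Hepatocyte identity and plasma protein genes (5 of 25 fell, median -0.44, random lists -0.51 to -0.17), acute phase genes (4 of 28 rose and 5 fell, median -0.47, random lists -0.49 to -0.18) and fatty acid oxidation and PPARA targets (2 of 37 rose and 2 fell, median -0.37, random lists -0.43 to -0.17) lay inside the range. The largest falls were Cfd (9.76 to 0.193 RPKM, log2 change -3.17), complement factor D, and Scd3 (6.62 to 0.0125 RPKM, log2 change -2.91), then LOC622167 (-2.85), Ces2a (-2.72), Ces1c (-2.49), Retsat (-2.42) and Adam11 (-2.42) beside the genes named above. The fall of Scd3 is uncertain, because its near-identical copy Scd1 was listed at 0 in flox high fat.

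**Figure D2:**
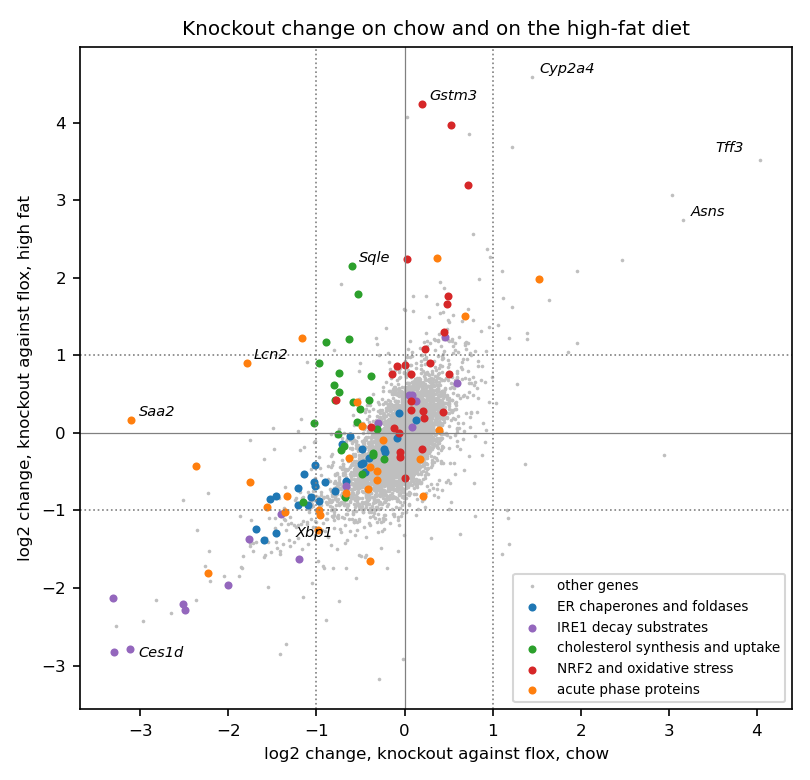
Each point is 1 gene, with its log2 change in knockout against flox livers on chow (x axis) and on the high-fat diet (y axis), members of 5 gene lists in colour and the threshold of 1 as dotted lines. Ces1d lies at -3.12 and -2.78, whereas Gstm3 lies at 0.20 and 4.24.

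In all, 111 genes rose and 192 fell among 10327 on the high-fat diet, and 25 of 34 lists stood apart. The split was 146 and 116 after rescaling to a median log2 ratio of 0 and 519 and 117 after rescaling without the 50 most abundant genes, so the balance of rises and falls depended on the scaling. Between the diets, 83 genes fell in knockout livers in both comparisons, where independent lists would share 2.58, and 18 rose in both, where independent lists would share 0.27. Another 4 genes passed the threshold in opposite directions. These 2 comparisons share no group.

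In flox livers the high-fat diet went with lower RNA levels of genes of the cholesterol synthesis pathway. 17 of 25 genes of cholesterol synthesis and uptake fell and 0 rose (median -1.65, random lists -0.18 to 0.02). Isopentenyl diphosphate isomerase, Idi1 (mm10 chromosome 13, 8885501 to 8892451), fell from 113 to 6.89 RPKM (log2 change -3.86), and squalene epoxidase, Sqle (30.7 to 1.79 RPKM, log2 change -3.51), from a lower level. Fdps (261 to 32.8 RPKM, log2 change -2.96), Nsdhl (-2.92), Cyp51 (-2.85), Sc4mol (-2.69), Hmgcs1 (-2.48), Mvd (-2.21) and Pmvk (-2.12) were the next largest falls; the retinoic acid hydroxylase Cyp26a1 (-2.03) also fell. Acss2, which makes acetyl-CoA from acetate, fell from 93.9 to 28.9 RPKM (-1.67). The iron hormone hepcidin, Hamp (7123 to 2282 RPKM, log2 change -1.64), was the 1 acute phase gene past the threshold among 28 (median -0.08, random lists -0.25 to -0.05).

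The largest rises with the diet in flox livers included genes of lipid transport. Apolipoprotein Apoa4 (113 to 433 RPKM, log2 change 1.93), the lysophospholipid transporter Mfsd2a (7.86 to 32.5 RPKM, log2 change 1.92), the sterol transporters Abcg5 (32.0 to 96.7 RPKM, log2 change 1.57) and Abcg8 (22.4 to 61.6 RPKM, log2 change 1.42), Rgs16 (1.82), 2010003K11Rik (1.67), Adam11 (1.66) and the acyl-CoA thioesterase Acot3 (1.36) rose. Fatty acid oxidation and PPARA targets stood apart on the high side, with 2 of 37 rising (median 0.22, random lists -0.20 to -0.02), as did lipid droplet genes (1 of 18 rising, median 0.14, random lists -0.17 to 0.06), where Cidec (0.989 to 3.74 RPKM, log2 change 1.25) rose, and lipoprotein genes (1 of 25 rising, median 0.06, random lists -0.23 to -0.01). Fatty acid synthesis stood apart on the low side (median -0.20, random lists -0.18 to 0.02), with a rise in Scd2 (0.723 to 3.36 RPKM) and falls in Acss2 and Elovl3 (-1.03). Scd3 (0.0156 to 6.62 RPKM, log2 change 2.91) and Cfd (0.533 to 9.76 RPKM, log2 change 2.81) rose the furthest of all genes named by the rule. Scd1, which at 929 RPKM in flox chow was the most abundant stearoyl-CoA desaturase gene, was listed at 0 in flox high fat, so the values of its near-identical copies there are uncertain.

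In flox livers, blood genes (median 0.36, random lists -0.29 to 0.11) stood apart on the high side and male-biased liver genes (median -0.37, random lists -0.26 to -0.01) on the low side. ER chaperones (median -0.20, random lists -0.17 to 0.02) and ER translocation genes (median -0.20, random lists -0.14 to 0.02) stood apart on the low side with 0 genes past the threshold. ATF4 and CHOP targets (median -0.02, random lists -0.10 to 0.08) and NRF2 genes (median -0.08, random lists -0.17 to 0.03) lay inside the range, the latter with Gstm3 (60.0 to 19.4 RPKM, log2 change -1.58) past the threshold. Macrophage markers (median 0.24, random lists -0.12 to 0.07) and endothelial markers (median 0.10, random lists -0.09 to 0.09) stood apart on the high side with 0 members past the threshold. Matrix genes (median 0.17, random lists -0.09 to 0.11) did too, with 0 rises and 0 falls, and so did inflammation and chemokine genes (median 0.12, random lists -0.07 to 0.11), with 0 rises and 1 fall. Periportal genes (median -0.36, random lists -0.24 to 0.00) stood apart on the low side, with 0 members past the threshold. In all, 22 genes rose and 44 fell among 10322, or 73 and 48 after rescaling without the 50 most abundant genes, and 18 of 34 lists stood apart.

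In knockout livers the diet went with a smaller decrease of the cholesterol pathway and with higher medians of the acute phase list and the list of NRF2 and oxidative stress. 7 of 25 genes of cholesterol synthesis and uptake fell (median -0.69, random lists -0.37 to -0.12), led by Sc4mol (108 to 32.4 RPKM, log2 change -1.71), Idi1 (78.1 to 26.3 RPKM, log2 change -1.54), Hmgcs1 (-1.37) and Mvk (-1.18). 7 of 28 acute phase genes rose and 2 fell (median 0.24, random lists -0.48 to -0.24), with Saa2 (197 to 1613 RPKM, log2 change 3.03), Lcn2 (26.6 to 184 RPKM, log2 change 2.75), Orm2 (2.37) and Saa1 (1.81). In knockout livers on the high-fat diet, Saa2 stood near its level in flox livers on that diet, 1433 RPKM, and Lcn2 above its flox level of 98.1 RPKM. 5 of 27 NRF2 genes rose (median 0.19, random lists -0.37 to -0.11), led by Gsta1 (2.74), Gstm3 (2.46), Cbr3 (2.41) and Gpx2 (2.21). S100g (4.24), Cyp2a4 (3.20), Ly6d (3.12), Gm3776 (2.83) and Apoa4 (70.5 to 405 RPKM, log2 change 2.50) completed the 10 largest rises. Here too Gm3776, which lies beside Gsta1, may not be a separate rise. Among ATF4 and CHOP targets, Ddit3 (5.78 to 18.0 RPKM, log2 change 1.49), Nupr1 (1.99) and Atf3 (1.17) rose and Asns (44.0 to 17.9 RPKM, log2 change -1.25) fell, and the list lay inside the range (median 0.00, random lists -0.22 to 0.01).

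ER chaperones stood apart on the high side in knockout livers on the diet, with 0 genes past the threshold (median 0.11, random lists -0.35 to -0.12), and Hspa5 was listed at 99.8 RPKM on chow and 136 RPKM on the diet. Fatty acid synthesis had 3 rises, Scd1 (264 to 894 RPKM, log2 change 1.75), Elovl5 (1.16) and Fads2 (1.07), and 1 fall, Elovl3 (85.5 to 18.7 RPKM, log2 change -2.13) (median 0.14, random lists -0.37 to -0.14). 5 of 37 fatty acid oxidation and PPARA targets rose, with Cyp4a31 (1.62), Acot3 (1.57), Cyp4a10 (1.56) and Cyp4a14 (1.29) ahead. The median of that list was -0.05 against -0.41 to -0.20 in random lists, and its sign turned positive under both rescalings.

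9 of 19 periportal genes fell with the diet in knockout livers (median -0.90, random lists -0.45 to -0.16), with Sds (108 to 34.2 RPKM, log2 change -1.62), Agxt2l1 (-1.53), Hal (-1.41) and Asl (-1.34). Macrophage markers rose in 4 of 24 cases (median 0.67, random lists -0.26 to -0.02), Marco (1.21), Cd14 (1.11), Cd5l (1.02) and Trem2 (1.01), and endothelial markers in 0 of 24 (median 0.11, random lists -0.21 to 0.02). Cholangiocyte markers (median 0.57, random lists -0.11 to 0.23), matrix genes (median 0.43, random lists -0.17 to 0.08) and cell cycle genes (median 0.54, random lists -0.12 to 0.16) stood apart on the high side. 3 of 6 blood genes (median below the random range of -0.53 to 0.03) and 8 of 17 male-biased liver genes (median -0.99, random lists -0.50 to -0.18) fell, while 3 of 7 female-biased liver genes rose (median 0.95, random lists -0.24 to 0.17). Only 7 of 20 female-biased genes entered, and 1 high group was enough to pass the filter. IRE1 decay substrates (median 0.33, random lists -0.34 to -0.02), with 0 past the threshold, inflammation and chemokine genes (3 rose, median 0.28, random lists -0.16 to 0.06) and stellate cell markers (1 rose, median 0.26, random lists -0.20 to 0.07) stood apart on the high side. Apoptosis and p53 targets did as well (2 rose, median 0.05, random lists -0.20 to 0.03). The largest falls were Selenbp2 (367 to 57.1 RPKM, log2 change -2.66), Elovl3, Moxd1 (-2.11), Mup21 (-1.89), Cyp8b1 (229.9 to 63.3 RPKM, log2 change -1.84), an enzyme of cholic acid synthesis, Phlda1 (-1.81), Ces2a (-1.79), Ear11 (-1.76), Sc4mol and the joined entry of the Raet1 genes (-1.69).

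In all, 69 genes rose and 82 fell among 10328 in knockout livers. The split was 96 and 60 after rescaling to a median log2 ratio of 0 and 396 and 62 after rescaling without the 50 most abundant genes, and 27 of 34 lists stood apart. Between the genotypes, 17 genes fell with the diet in both, where independent lists would share 0.33, and 5 rose in both, where independent lists would share 0.13.

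The interaction set the knockout change on the high-fat diet against that on chow, without a test. Cholesterol synthesis had the most members past the threshold, 11 of 25, all higher (median 0.82, random lists -0.28 to -0.06), with Sqle at 2.76, Idi1 at 2.32, Cyp51 at 2.07 and Fdps at 1.87. Acute phase genes (6 of 28 higher and 2 lower, median 0.33, random lists -0.33 to -0.08) and NRF2 genes (7 of 27 higher, median 0.61, random lists -0.28 to -0.03) followed. The largest medians were those of female-biased liver genes (4 of 7 higher, median 1.41, random lists -0.24 to 0.13) and blood genes (4 of 6 lower, median -1.26, random lists -0.43 to 0.09). Periportal genes (2 of 19 lower, median -0.61, random lists -0.33 to -0.04) and male-biased liver genes (5 of 17 lower, median -0.61, random lists -0.38 to -0.04) stood apart on the low side. Gstm3 (4.04), S100g (4.04), Gsta1 (3.45), Saa2 (3.27) and Cyp2a4 (3.14) were the 5 largest positive values. Scd3 (-2.90), Cfd (-2.89), Moxd1 (-2.61), Rprl3 (-2.27) and Ear11 (-2.16) were the 5 largest negative ones. The Scd3 value rests on flox high fat, where Scd1 was listed at 0, and is uncertain. Rprl3 is annotated as a ribozyme gene, and its symbol was not among those left out as small RNA genes. ER chaperones stood apart on the high side (median 0.24, random lists -0.26 to -0.05) with 0 members past the threshold, as did IRE1 decay substrates (median 0.34, random lists -0.27 to 0.01) with 1, Ces1g (1.19). Lipid droplet genes (median -0.49, random lists -0.28 to -0.03), with Cidec (-1.19), Fitm1 (-1.10) and G0s2 (-1.01) past the threshold, and fatty acid oxidation and PPARA targets (median -0.40, random lists -0.30 to -0.08) stood apart on the low side. In the latter list 3 members went past the threshold on the high side, Cyp4a31 (2.05), Cyp4a14 (1.87) and Cyp4a10 (1.45), and 1 on the low side, Acaa1b (-1.01). Bile acid genes stood apart on the low side (3 lower, median -0.34, random lists -0.29 to -0.04). Fatty acid synthesis (2 higher and 1 lower, median 0.29, random lists -0.28 to -0.06) and cell cycle genes (3 higher, median 0.46, random lists -0.13 to 0.12) stood apart on the high side. So did macrophage markers (1 higher, median 0.40, random lists -0.22 to 0.00), cholangiocyte markers (1 higher, median 0.43, random lists -0.12 to 0.18) and matrix genes (1 higher, median 0.36, random lists -0.17 to 0.05), and by smaller margins stellate cell markers (median 0.19, random lists -0.19 to 0.05), inflammation and chemokine genes (median 0.16, random lists -0.17 to 0.02) and endothelial markers (median 0.02, random lists -0.19 to 0.00). In all, 25 of 33 lists stood apart.

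**Figure D3:**
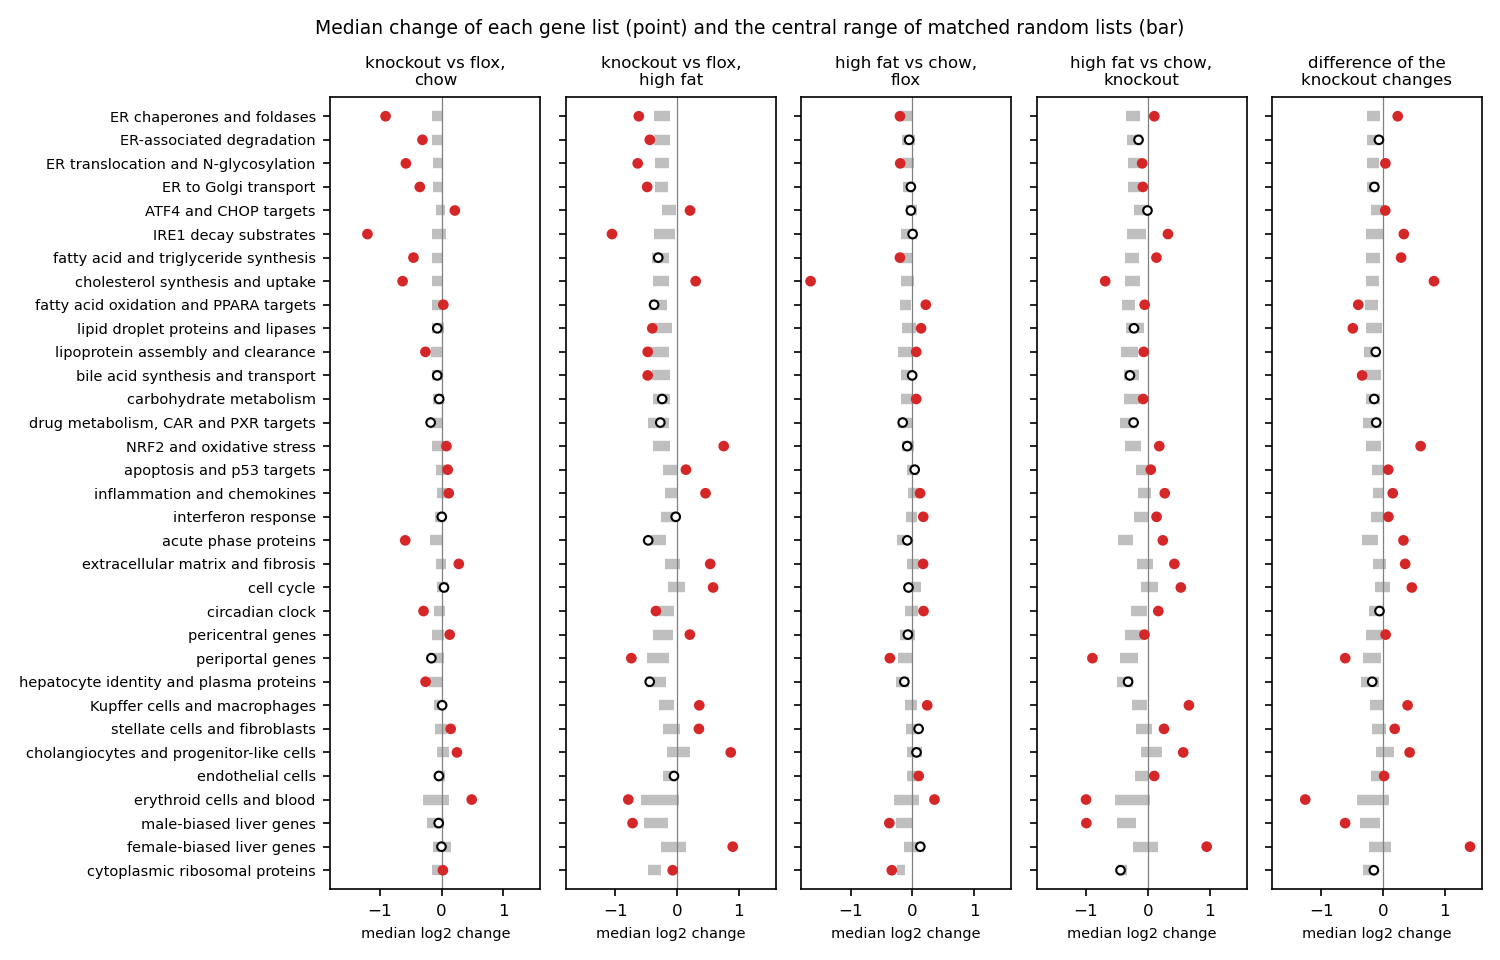
Points are the median log2 change of each of 33 gene lists in the 5 comparisons (panels), bars the range between the 2.5 and 97.5 percentiles of matched random lists, and red points lie outside the bar. The cholesterol list runs from -1.65 for the diet in flox livers to 0.82 for the difference of the knockout changes.

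In all, the interaction was at least 1 in 68 genes and at most -1 in 59 among 10319. The split was 95 and 36 after rescaling to a median log2 ratio of 0 and 255 and 58 after rescaling without the 50 most abundant genes.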

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

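The bounds for both tests in this part were set before their results were seen, and the search for opposite changes was made afterwards. In 17 genes the knockout change was at least 1.5-fold on both diets but in opposite directions, with at least 5 RPKM in at least 1 group. The difference was not tested, since each group has 1 value. At 1.5-fold and without the limit of 5 RPKM, 113 genes were higher and 396 lower in knockout livers on chow, and 330 and 860 on the high-fat diet. The number of opposite pairs expected from independent lists was not computed, so the 17 are not shown to exceed it. The log2 knockout change is given on chow and then on the high-fat diet.

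Cholesterol synthesis genes were lower in knockout livers on chow and higher on the high-fat diet. They were Sqle (-0.60 and 2.16, difference 2.76), Cyp51 (-0.89 and 1.18, difference 2.07), Fdps (-0.98 and 0.90, difference 1.87), Nsdhl (-0.63 and 1.22, difference 1.85), Mvd (-0.74 and 0.77, difference 1.52) and Lss (-0.80 and 0.62, difference 1.41). The acute phase genes Lcn2 (-1.79 and 0.90, difference 2.69) and Orm2 (-1.16 and 1.23, difference 2.39), the fatty acid hydroxylases Cyp4a31 (-0.90 and 1.15, difference 2.05) and Cyp4a14 (-0.80 and 1.07, difference 1.87), which belong to a family with near-identical members, and Derl3 (-1.10 and 0.91, difference 2.02) of ER-associated degradation moved the same way. In the other direction went Moxd1 (1.18 and -1.43, difference -2.61), the ribozyme gene Rprl3 (1.18 and -1.10, difference -2.27), Ear11 (1.17 and -0.99, difference -2.16), Arrdc3 (0.80 and -1.07, difference -1.86), 2010003K11Rik (0.79 and -0.64, difference -1.43) and the joined haemoglobin entry Hbb-b1,Hbb-b2 (0.63 and -1.31, difference -1.93).

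The cholesterol pattern was weighed against 2 technical explanations. A difference in scaling between the files would move all genes alike. If it had caused the pattern, the list's median interaction of 0.82 would have come to 0.20 or less after rescaling. It came to 0.961 (95% bootstrap interval over the 25 genes 0.64 to 1.41). The median interaction of all genes was -0.10, so this rescaling could only raise the list's median. Bootstrap intervals here and below resample the genes of a list and hold no spread between mice or libraries. After a smooth trend with transcript length, GC content and expression was removed, which held 6.60% of the variance of the interaction, the median was 0.995 (0.71 to 1.43). The median of all genes, opposite in sign to that of the list, argues against a common difference in scaling. The value after removal of the trend argues against such a trend. The fit also took out the shift common to all genes, which by itself raises the list's median. A difference between pools of mice that has nothing to do with genotype or diet stays open, because no value per library was analysed here, and a response to the diet that depends on Xbp1 may also account for the pattern and was not tested.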

How the results depend on the processing

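The zeros kept at 0 and the omission of small RNA genes were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the files hold 1 pooled value per group and no column of a single replicate. For the same reason leaving out each replicate, the fits with and without a trend and the count-based tests planned for other kinds of file were not run.

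The counts of genes past the threshold depended on the pseudocount and the threshold. In the order knockout on chow, knockout on high fat, diet in flox, diet in knockout and interaction, they were 167, 303, 66, 151 and 127 as reported. With a pseudocount of 0.1 they were 263, 494, 124, 305 and 240, and with one of 5 they were 96, 156, 40, 85 and 68. A threshold of 1.5-fold gave 509, 1190, 300, 762 and 552. These shifts follow from the construction, since a smaller pseudocount lets more low genes pass. Rescaling without the 50 most abundant genes gave 215, 636, 121, 458 and 313. It multiplied the values by 3.14 to 4.26, which also shrinks the pseudocount relative to them, and the 2 effects were not tested apart. The genes shared by the knockout comparisons (101 as reported) numbered 168, 66 and 367 with the pseudocounts of 0.1 and 5 and the 1.5-fold threshold, and those shared by the diet comparisons (22) numbered 43, 13 and 104, and 37 under rescaling without the top genes.

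No filter, a filter of 5 RPKM, rescaling to the median, the choice of repeated row, zeros kept at 0 and small RNA genes left out kept each total within 1.5 times. A gene below 1 RPKM in all 4 groups cannot reach a log2 change of 1 with a pseudocount of 1. Leaving out the filter therefore could not alter the counts of any comparison between 2 groups. The 2 directions moved further in 3 cases. With the filter of 5 RPKM, 64 genes in place of 111 rose in knockout livers on high fat, and with rescaling to the median 116 in place of 192 fell there and 36 in place of 59 had a negative interaction. The fall of Xbp1 ranged from -1.10 to -1.41 over both diets and all settings. For the lists, percentiles were recomputed only with both other pseudocounts, with rescaling to the median and with the coarser matching bins. Of these, 668 of 676 percentile results kept their side of the range, 4 left it, 4 entered it and 0 changed side. Rescaling to the median shifts a list and its random lists nearly alike, so agreement under it was largely built in. The percentiles were not tested under rescaling without the top genes or the remaining alternatives. Of 7325 results for named genes, 6815 kept direction and side of the threshold, 331 came to pass it, 153 no longer did and 26 small changes under the threshold changed sign under rescaling. Much of that agreement was fixed in advance. A gene's own change does not depend on the filter, on zeros kept at 0 or on small RNA genes left out. The choice of repeated row matters only for a repeated symbol. All 746 results of each such setting, and all 611 of the filter of 5 RPKM, were unchanged and are no evidence of stability. Depth is unknown, so genes near 1 RPKM carry a counting error that cannot be given.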

Other observations

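The Xist test and the comparison of macrophage with endothelial markers were chosen after the results were seen, and the bounds of the other tests in this part before.

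Several lists fit in no comparison above. Clock genes were lower in knockout livers on chow (median -0.29, random lists -0.12 to 0.05) and on high fat (median -0.34, random lists -0.29 to -0.05). They were higher with the diet in flox livers (median 0.18, random lists -0.12 to 0.08) and in knockout livers (median 0.17, random lists -0.26 to -0.02), with 0 genes past the threshold in each. Pericentral genes stood apart on the high side in knockout livers on chow (median 0.13, random lists -0.15 to 0.05) and on the high-fat diet (median 0.21, random lists -0.39 to -0.06), although Cyp2e1 (-1.20 on chow and -1.63 on high fat) and Cyp1a2 (-1.41 and -1.05) fell on both. Glutamine synthetase, Glul, went from 368 to 677 RPKM on high fat. Interferon response genes lay inside the range on both knockout comparisons (median 0.00, random lists -0.10 to 0.05 on chow and median -0.02, random lists -0.25 to -0.02 on high fat), and the sign of the latter median turned positive under both rescalings. They stood apart on the high side with the diet in flox livers (median 0.18, random lists -0.11 to 0.08) and in knockout livers (median 0.14, random lists -0.23 to 0.00) and for the interaction (median 0.09, random lists -0.20 to 0.00). The carbohydrate list lay inside the range in knockout livers on high fat (median -0.24, random lists -0.38 to -0.11), with a rise in Igfbp1 (7.52 to 49.7 RPKM, log2 change 2.57), the gene of an insulin-like growth factor binding protein, and a sign that turned under rescaling without the top genes. Drug metabolism genes had 2 rises and 2 falls in knockout livers on high fat (median -0.27, random lists -0.47 to -0.14). Ribosomal protein genes stood apart on the low side with the diet in flox livers (median -0.33, random lists -0.24 to -0.12). They stood apart on the high side in both knockout comparisons (median 0.02, random lists -0.16 to -0.03 on chow and median -0.07, random lists -0.47 to -0.26 on high fat), and the sign of the latter median turned positive under both rescalings. Their median lay inside the range with the diet in knockout livers (median -0.44, random lists -0.48 to -0.33) and for the interaction (median -0.15, random lists -0.32 to -0.13).

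Female-biased liver genes stood apart on the high side in knockout livers on the high-fat diet, with 2 of 7 rising, Cyp2a4 and Cyp2b9 (1.36) (median 0.90, random lists -0.26 to 0.15). These 7 were the only members of 20 that entered, and a member could pass the filter through that group alone. Their median on chow was 0.00. Y-linked genes (4 measured) had a median change of -0.20 in knockout livers on high fat, a value whose sign turned under rescaling without the top genes. Markers of lymphocytes (4 measured, median 0.36), neutrophils (2 measured, median -0.16) and adipose tissue, pancreas, muscle and mesothelium (4 measured, median -0.95) were too few for random lists, and the sign of the neutrophil median turned under rescaling without the top genes. For the mitochondrial genome, 0 genes were measured. Blood genes had a median of 0.49 in knockout livers on chow and -0.79 on high fat, with the joined entry Hba-a1,Hba-a2 at 1591 and 772 RPKM in the 2 knockout groups.

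Some values are hard to read as expression. The microRNA gene Mir135a-1 was listed at 17762 RPKM in knockout high fat, above every other entry of that group, and at 0 in the other 3 groups. Small RNA genes had a median of -0.06 in knockout livers on high fat over 8 genes, inside the random range, and its sign turned under both rescalings. They stood apart on the low side in knockout livers on chow (median -0.36, random lists -0.26 to 0.16), where the sign turned under rescaling without the top genes, and with the diet in knockout livers (median -0.40, random lists -0.36 to 0.13). Apoe was listed at 13172 RPKM in flox chow and 11145 RPKM in knockout chow and at 0 in both groups on the high-fat diet, and Serpina1 genes were listed at 0 in some groups and at high values in others, such as Serpina1e at 0 in flox chow and 10004 RPKM in flox high fat.

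Periportal and male-biased genes were lower in knockout livers on the high-fat diet, with a pooled median of -0.73 over 37 genes. Female mice in that group are argued against by Xist, whose highest value over the 4 groups was 0.043 RPKM. After removal of a smooth trend with transcript length, GC content and expression, which held 14.0% of the variance, the pooled median was -0.385 (95% bootstrap interval over genes -0.52 to -0.26), between the bounds set for and against that explanation. The fit also took out the shift common to all genes (median -0.13), which by itself raises list medians. The trend and a change specific to these lists cannot be told apart on the pooled median. An effect of Xbp1 loss on this diet, or a difference between the pools, may contribute, and neither was tested.

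Cholangiocyte, macrophage and matrix genes were higher in knockout livers on the high-fat diet, with a pooled median of 0.49 over 62 genes. A lower share of hepatocytes would raise markers of every other cell type alike. The macrophage median exceeded the endothelial one by 0.409 (95% bootstrap interval over genes 0.25 to 0.60), so these lists did not rise alike. The pair was chosen after both medians were known, so the difference restates them and is not a test. A lower share of hepatocytes stays open. Removing the trend with length, GC content and expression left 0.612 (0.51 to 0.73), which argues against that trend. The fit also took out the shift common to all genes, which by itself raises the pooled median. A change in the number of duct cells and macrophages, or in expression within cells, may account for the pattern as a hypothesis, and a difference between the pools stays open because no value per library was analysed here.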
